A study of Mus musculus with 6 samples.

How the data were processed

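Each of the 6 libraries came from 1 cortical hemisphere of a pup at postnatal day 2, of the C57BL6/J strain per the labels. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase, and made into strand-specific polyA libraries with the Lexogen SENSE mRNA-Seq kit, which were sequenced on an Illumina HiSeq instrument. The series' design text calls the 3 samples of each genotype biological replicates, and names the control mice wild type where the genotype label gives floxed alleles without Cre.

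The deposited values are raw counts of reads per gene, not normalised, in the layout of STAR's gene counting, with 1 table per library. STAR 2.5.4 and the builds GRCm38 and mm10 are named, per the submitters' processing notes. The annotation release and filters on reads are not given in the sources used here. Each table lists 52550 gene identifiers with counts on either strand, on the strand of the first read and on the opposite strand, after 4 summary lines for unmapped, multi-mapping, unassigned and ambiguous reads. The summary lines were kept out of library sizes and tests. Reads outside annotated exons on the strand used, called reads outside exons below, were 22.5 to 27.9% of the mapped reads. They can lie in introns, between genes or on the opposite strand of a gene, which was not resolved. Unmapped reads were 26.1 to 27.7% of the reads listed, and ambiguous reads 0.689 to 0.759% of the mapped ones. The multi-mapping line was 0 in every table, so reads shared between near-identical copies are not counted for any of them, and such genes are undercounted. By a rule set before the data were examined, the strand column with more reads was used; it held 18.6 times as many as the other, so overlapping genes on opposite strands were told apart. Gene symbols, coordinates and types came from GENCODE M21 on GRCm38, in which 52403 identifiers were found without their version.

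Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (14913 genes), libraries were scaled by TMM (factors 0.979 to 1.04), and genotypes were compared with the robust quasi-likelihood F-test, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. CPM values use the TMM-scaled library sizes. The SE of a log2 change is its size divided by the square root of F. Total gene counts were 8249436 to 10372582 per library. The 36 gene lists, 21 of pathways, 14 of cell types or regions and 1 of library quality, were written before the data were examined and hold 865 entries, 5 of them with no matching gene. They were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over all 36 lists, and again with camera's estimated correlation and with fry, whose directional p asks whether a list's genes move 1 way on balance. Median pair differences are medians over a list's genes of log2 CPM in a knockout minus that in the control of the same letter. Whole-library measures were compared with exact two-sided permutation tests of the difference in means.

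The genes named were chosen by a rule written before the data were examined. Slc7a5 came first. Then came up to 12 genes in each direction with the largest change among those past the threshold, with non-overlapping groups and a mean of at least 1 CPM, and, where fewer than 5 passed in a direction, the 5 with the smallest p. From every list that passed, the 4 members with the smallest p were named, from other lists any called member or, without one, the 2 with the smallest p. Symbols beginning with Gm and a digit or ending in Rik were counted but not named; Gm26812 was named because it was 1 of only 5 calls. Some genes that the rule names are not reported here.

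Both genotypes carry the letters A, B and C in their titles, so a fit with the letter as a block was planned as an alternative to the group-only fit. Before calls were compared, the deviations of the libraries from their group means were correlated across genes. Control and knockout of the same letter correlated at 0.417, 0.342 and 0.211 for A, B and C, and no pair of different letters reached above -0.0310. Without genes of the X and Y chromosomes the values were 0.393, 0.242 and 0.182, with at most 0.0360 between different letters. The letters were therefore taken to pair the libraries, by this check of the data, since the labels do not say what they mark. Deviations from a group mean cancel within each genotype, so the values between different letters follow in part from those of the same letter. With so few letters the check cannot establish the pairing. Both libraries of letter B had Xist at 918 and 961 CPM (a transcript of the inactive X chromosome of females), and the others at most 2.95 CPM. No 2 libraries agreed within sampling noise (chi-square per degree of freedom at least 4.03), so each counts as 1 replicate.

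The fits were tested on simulated counts built from the means, library sizes and dispersions of these libraries. The means held the letter effects, and the dispersions came from the paired fit. In each of 5 simulations 200 genes were changed 1.5-, 2- or 4-fold among the 14913 genes. Recovery is given with the results. In both fits 5 of 5 simulated lists with a 1.3-fold change were called and 0 of 175 unchanged lists. Genes were simulated independently and lists drawn at random, so this does not test camera's preset correlation on lists of correlated genes. In the real data the estimated correlation was 0.21 for the amino acid response list and 0.0026 for the interneuron list.

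Alternatives written before the data were examined were the replicate block, unstranded counts, other size factors (RLE and upper quartile), no filter and a filter of 1 CPM in 3 libraries. Also planned were leaving out each library, DESeq2 1.42.0, limma-voom, other thresholds, and removal of Xist, Tsix and genes of the Y chromosome. The last were offsets for GC content and gene length, values of which were found for 99.9% of tested genes. Alternatives chosen after seeing the data were protein-coding genes alone, the share of reads outside exons as a covariate, and, within the paired fit, the same choices other than the offsets for GC content and gene length, which were planned with the block.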

Results

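Polyadenylated RNA was sequenced from the cortex of mouse pups at postnatal day 2, with 1 cortical hemisphere per library. Mice that carried floxed alleles of Slc7a5 and the Cre recombinase under Emx1 control formed the knockout group (n = 3), and floxed mice without Cre formed the control group (n = 3). Emx1-driven Cre acts in the progenitors that give rise to the excitatory neurons, astrocytes and part of the oligodendrocytes of the dorsal forebrain, and leaves microglia, blood vessels and most cortical interneurons unrecombined. Slc7a5 encodes the light chain of LAT1, a transporter that exchanges large neutral amino acids such as leucine across the plasma membrane. The titles give the libraries the letters A, B and C in each genotype. Gene counts per library were 10077443, 8249436 and 9927206 in controls A, B and C, and 9851376, 10372582 and 9524407 in knockouts A, B and C. The comparison asks which transcripts differ in the newborn cortex when this transporter is removed from the Emx1 lineage. Every knockout carries Cre and no control does, so effects of the Cre allele cannot be told apart from those of the deletion.

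Slc7a5 (ENSMUSG00000040010, GRCm38 chromosome 8 from 121881150 to 121907694, minus strand) was lower in each of the 3 knockout libraries than in each of the 3 control libraries. Its level was 20.2, 40.7 and 26.1 CPM (counts scaled to library size) in controls A, B and C, and 15.6, 9.37 and 11.4 CPM in the corresponding knockouts. The group means were 29.0 ± 10.5 and 12.1 ± 3.20 CPM (SD, n = 3), a log2 change of -1.25 ± 0.28 (SE). The controls of this gene spread widely, and the difference did not pass edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment over all genes (adjusted p = 0.400), nor with the letter as a block (adjusted p = 0.421). It passed with DESeq2 (adjusted p = 4.17e-04) and in edgeR without the filter on low counts (adjusted p = 5.02e-11), and adjusted p ran from 0.0687 to 0.679 when 1 library at a time was left out. The counts cover the whole gene, the labels do not say which exons are floxed, and the cortex holds cells outside the Emx1 lineage.

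**Figure D1:**
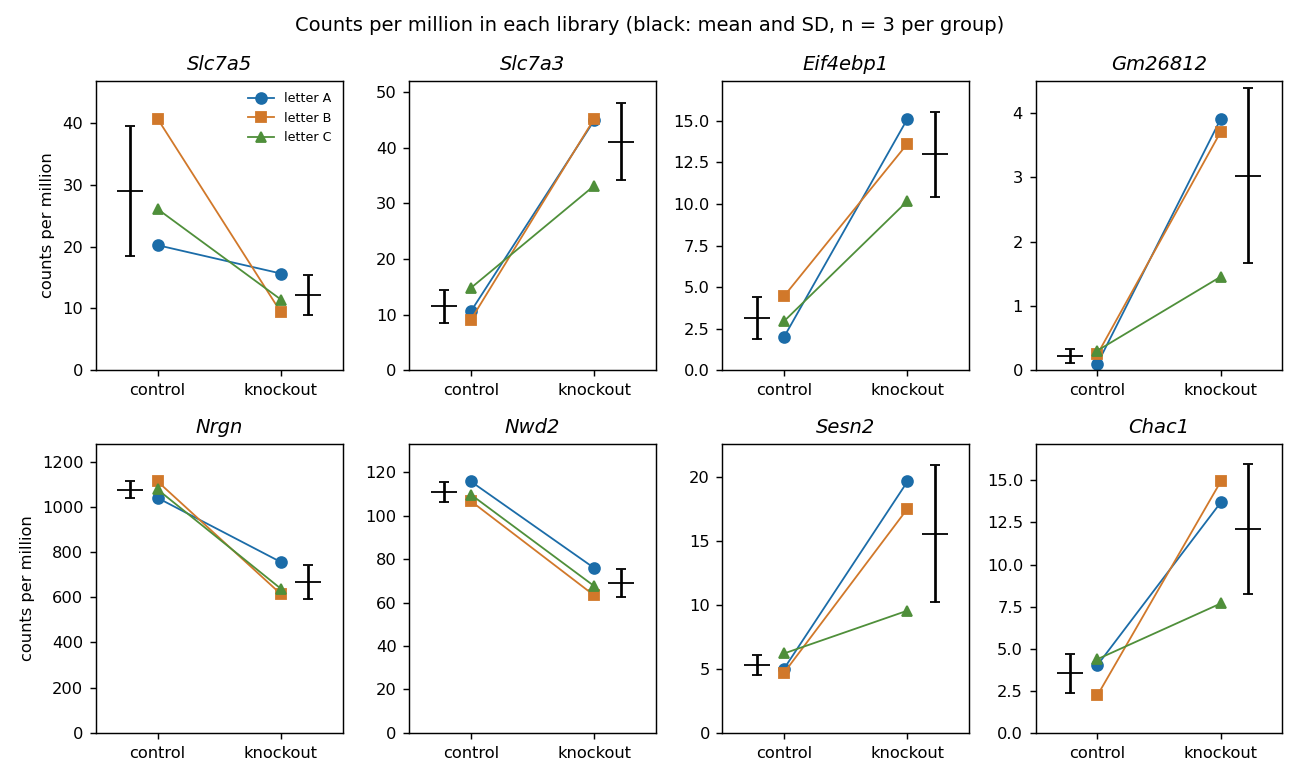
CPM (y axis, linear, from 0) of 8 genes in control and knockout libraries (x axis). Each coloured symbol is 1 library, lines join libraries of the same letter, and black bars give the mean and SD of 3 libraries. In all 8 panels the 3 knockout libraries lie on 1 side of the 3 controls. Slc7a5, Sesn2 and Chac1 did not pass the unpaired test. Apart from Slc7a5, the genes were chosen for calls with non-overlapping groups or for small p. Among all 14913 tested genes, 879 had every knockout above and 937 every knockout below every control, where 10% would separate so by chance.

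Among 14913 genes tested, 5 passed the threshold in edgeR's quasi-likelihood test, 3 higher and 2 lower in the knockout. Slc7a3, a carrier of cationic amino acids (ENSMUSG00000031297, chromosome X from 101079210 to 101086020, minus strand), rose from 11.5 ± 2.96 to 41.1 ± 6.86 CPM (SD, n = 3), a log2 change of 1.83 ± 0.18 (SE, adjusted p = 5.65e-04). Eif4ebp1, which encodes the translation repressor 4E-BP1 (ENSMUSG00000031490, chromosome 8 from 27260329 to 27276674, plus strand), rose from 3.14 ± 1.24 to 13.0 ± 2.54 CPM, by 2.06 ± 0.26 on the log2 scale (adjusted p = 0.00445). The third was Gm26812, a long intergenic noncoding RNA described further on. Nrgn, the postsynaptic calmodulin-binding protein neurogranin (ENSMUSG00000053310, chromosome 9 from 37544492 to 37552904, minus strand), fell from 1076 ± 36.4 to 669 ± 75.9 CPM, with a log2 change of -0.69 ± 0.11 (adjusted p = 0.0196). Nwd2 (ENSMUSG00000090061, chromosome 5 from 63649102 to 63810546, plus strand) fell from 111 ± 4.61 to 69.0 ± 6.41 CPM, with a log2 change of -0.68 ± 0.10 (adjusted p = 0.0196). The next genes by p did not pass. They were, higher in the knockout, Sesn2, a leucine sensor of the mTORC1 pathway (1.54 ± 0.25, adjusted p = 0.0506), and Chac1, an enzyme that degrades glutathione (1.75 ± 0.29, adjusted p = 0.0506), and, lower, the adaptor Dok4 (-0.53 ± 0.10, adjusted p = 0.0841), the metabotropic glutamate receptor Grm2 (-0.90 ± 0.17, adjusted p = 0.0942) and the layer 4 transcription factor Rorb (-0.64 ± 0.12, adjusted p = 0.0942).

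The letters were taken to pair the libraries, and with the letter as a block 126 genes passed in the same test, 49 higher and 77 lower, including all 5 above and Sesn2, Chac1, Dok4, Grm2 and Rorb (adjusted p from 2.39e-04 to 0.00115 for the last 5). The paired calls with lower counts were all protein-coding genes, whereas 26 of the 49 higher ones were protein-coding and 17 were TEC loci, a GENCODE class of provisional transcripts that await experimental checks. On simulated data the unpaired fit found 18.4%, 64.5% and 90.4% of genes changed 1.5-, 2- and 4-fold, with 0.171% false calls, and the paired fit found 51.1%, 84.3% and 98.0% with 9.82% false calls, above the nominal 5%. Letter effects were built into the simulated counts, so the higher recovery of the paired fit does not show that the letters pair these libraries. Without pair A the paired count was 228 (88 higher, 140 lower), and without pair C it was 77 with the balance turned (46 higher, 31 lower). DESeq2 called 30 genes with the block and 24 without, 23 of the latter among the 126. The unpaired count was 2 without control A, 2 without control B, 1 without knockout B and 9 without knockout C, where Sesn2 and Chac1 passed (adjusted p = 1.39e-04 and 4.63e-04). Slc7a3 passed with any 1 library left out. Eif4ebp1 was lost without knockout B (adjusted p = 0.0600). Nrgn and Nwd2 were each lost without any 1 control or without knockout B, Nrgn also without knockout C, with adjusted p of up to 0.146 and 0.132 without control B.

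Genes of the amino acid response, targets of the transcription factor ATF4, were the list with the largest median change. Of 29 tested members 27 had higher and 2 lower values in the knockout, with a median log2 change of 0.52 and pair medians of 0.58, 0.57 and 0.23 for letters A, B and C (camera adjusted p = 6.67e-35, adjusted p = 0.109 with an estimated correlation). Slc7a3 and Eif4ebp1 passed over all genes, 15 members were called higher when adjusted over the list alone, and 10 were called higher over all genes in the paired fit. Besides Sesn2 and Chac1, these included Atf5 (1.16 ± 0.18, paired adjusted p = 1.74e-08), asparagine synthetase Asns (0.85 ± 0.17, 0.0215), the mitochondrial one-carbon enzymes Shmt2 (0.75 ± 0.16, 2.39e-04) and Mthfd2 (0.71 ± 0.13, 8.24e-04), the serine synthesis enzyme Psat1 (0.50 ± 0.12, 0.0111) and the proline synthesis enzyme Pycr1 (0.73 ± 0.21, 0.00746), named after their values were seen. Atf4 itself had a log2 change of 0.24 ± 0.13 (adjusted p = 0.742). The cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, rose as a list, with 15 of 20 members higher (median 0.19, camera adjusted p = 3.59e-06, adjusted p = 0.129 with an estimated correlation). No member passed over all genes and 6 passed adjusted over the list alone. Cars (0.59 ± 0.12) passed in the paired fit (adjusted p = 0.00276), and the values of Lars, Eprs and Yars were 0.35 ± 0.10, 0.32 ± 0.10 and 0.30 ± 0.095.

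The large neutral amino acid carriers and their partners, a list that holds Slc7a5 itself, fell, with 7 of 10 members lower (median -0.21, camera adjusted p = 0.00886, adjusted p = 0.197 with an estimated correlation). Besides Slc7a5, the values were -0.33 ± 0.14 for Slc7a8, -0.41 ± 0.17 for Slc3a2, which encodes the heavy chain of LAT1, and -0.40 ± 0.18 for Slc6a15. The 1 member that passed adjusted over the list alone was Slc7a5 itself. The list kept its call, with a smaller median, without control B (-0.13), without the genes in more than 1 list (-0.083) and without the filter on low counts (-0.053). Slc7a5 stayed in the list in each of these fits, and the list was not tested without it. A fall of the carriers other than the deleted one was therefore not shown. The other amino acid carriers did not pass as a list (21 tested, median 0.029, camera adjusted p = 0.0648), although Slc7a3 belongs to it. They passed without control B (0.0317), control C (0.0153) or knockout A (0.0254), and their median ranged from -0.034 to 0.079 with 1 library left out.

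Cholesterol synthesis genes had lower values in all 24 of 24 tested members (median -0.22, pair medians -0.059, -0.33 and -0.17, camera adjusted p = 1.74e-07, adjusted p = 0.271 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The changes were small, with -0.40 ± 0.14 for Mvd, -0.42 ± 0.15 for Nsdhl, -0.30 ± 0.12 for Acat2 and -0.23 ± 0.10 for Hmgcs1, the synthase upstream of the rate-limiting reductase. Fatty acid and glycerolipid synthesis fell as well, with 22 of 30 members lower (median -0.13, camera adjusted p = 0.00886, adjusted p = 0.197 with an estimated correlation). Its values were -0.43 ± 0.11 for Acsl4, which passed in the paired fit (adjusted p = 0.0261), -0.31 ± 0.12 for Scd2, -0.39 ± 0.17 for Scd1 and -0.30 ± 0.14 for fatty acid synthase Fasn, and the list was lost without knockout B (median -0.085, camera adjusted p = 0.0730). Weaker calls of lower lists were the unfolded protein response (16 of 23 lower, median -0.11, camera adjusted p = 0.0221, adjusted p = 0.226 with an estimated correlation) and the tricarboxylic acid cycle (20 of 26 lower, median -0.085, camera adjusted p = 0.0268, adjusted p = 0.281 with an estimated correlation). Their members Xbp1 (-0.34 ± 0.10), Edem1 (-0.57 ± 0.20), Manf (-0.36 ± 0.14) and Pdia6 (-0.18 ± 0.10), and Idh1 (-0.34 ± 0.11), Mdh2 (-0.27 ± 0.11), Pcx (-0.24 ± 0.14) and Dlat (-0.19 ± 0.12), did not pass. The first list was lost without control B (0.0963), knockout A (0.0596) or knockout C (0.0532), and the second without control C (0.0629), knockout A (0.206) or knockout C (0.0700). The median of the first was -0.040 without control B, and that of the second -0.15 without knockout B.

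Among neuronal lists, markers of upper-layer projection neurons fell, with 16 of 20 members lower, a median of -0.20 and pair medians of -0.18, -0.18 and -0.23 (camera adjusted p = 3.59e-06, adjusted p = 0.226 with an estimated correlation). Besides Rorb, the values were -0.40 ± 0.11 for Rasgrf2, -0.32 ± 0.10 for the transcription factor Mef2c and -0.37 ± 0.14 for Plxnd1. In the list 3 members passed adjusted over the list alone, and 3 passed over all genes in the paired fit. Markers of deep-layer projection neurons did not pass (10 of 19 lower, median -0.061, camera adjusted p = 0.437), with -0.68 ± 0.24 for Cplx3 and -0.23 ± 0.10 for Sox5. Their pair medians were -0.11, -0.10 and -0.0073. Their median was -0.037, -0.0092 and -0.028 without control B, knockout A and knockout C, and 0.033 without the genes in more than 1 list. The upper-layer minus deep-layer difference of the pair medians averaged -0.124 ± 0.0830 (SD, 3 pairs), so a fall specific to upper layers was not shown. Activity-regulated genes fell, with 22 of 27 members lower (median -0.17, camera adjusted p = 2.64e-04, adjusted p = 0.122 with an estimated correlation). The immediate early genes Egr4, Egr3 and Nr4a3 had values of -0.59 ± 0.24, -0.46 ± 0.18 and -0.25 ± 0.11, and Inhba of -0.37 ± 0.16, none of which passed alone. Thyroid hormone-induced genes fell (11 of 15 lower, median -0.10, camera adjusted p = 0.00886, adjusted p = 0.226 with an estimated correlation). They hold Nrgn, Sema7a (-0.40 ± 0.13, paired adjusted p = 0.0375), Hr (-0.81 ± 0.28) and, in the other direction, the hormone-inactivating deiodinase Dio3 (0.62 ± 0.18). That list was lost without control C (0.0871) or knockout B (0.0576) and without the genes that belong to more than 1 list (0.129). Its median was -0.22, -0.20 and -0.21 without control A, control B and knockout A, and -0.048 without knockout B.

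Voltage-gated and related ion channels were called lower as a list (26 of 46 lower, median -0.046, camera adjusted p = 0.0280, adjusted p = 0.403 with an estimated correlation), but the call was lost without control A (0.359), knockout B (0.0710) or knockout C (0.154). Its median was 0.0072, -0.085 and -0.072 without controls A, B and C, and -0.021 without knockout C. The small-conductance potassium channel Kcnn1 (-0.81 ± 0.24, paired adjusted p = 8.08e-04) and the T-type calcium channel Cacna1g (-0.41 ± 0.11, 0.0444) passed in the paired fit, and the inward rectifiers Kcnj4 and Kcnj3 had values of -0.47 ± 0.15 and -0.36 ± 0.11. The excitatory synapse list, which also holds Nrgn, did not pass unpaired (32 tested, median -0.024, camera adjusted p = 0.0714) and passed paired (adjusted p = 0.0268, 0.396 with an estimated correlation). It also passed without control B (0.0260) or knockout A (0.0257), and its median ranged from -0.057 to 0.011 with 1 library left out. The inhibitory synapse receptors did not pass (20 tested, median -0.015, camera adjusted p = 0.733), with 0.35 ± 0.14 for Gabra2 and -0.24 ± 0.13 for Glrb.

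Interneuron markers rose, with 22 of 24 members higher, a median of 0.19 and pair medians of 0.21, 0.25 and 0.073 (camera adjusted p = 6.15e-06, adjusted p = 0.109 with an estimated correlation). Gad2, a glutamate decarboxylase that makes GABA, had 0.51 ± 0.16 and passed in the paired fit (adjusted p = 0.0191). Without control B its value was 0.33. The transcription factors Dlx6 and Dlx1 had 0.40 ± 0.16 and 0.27 ± 0.11. Radial glia and intermediate progenitor markers were called higher (16 of 19 higher, median 0.14, camera adjusted p = 0.00886, adjusted p = 0.281 with an estimated correlation), with 0.74 ± 0.24 for Eomes, 0.33 ± 0.13 for Nes, 0.30 ± 0.12 for Vim and 0.31 ± 0.12 for Sox2. They were lost without control A (0.119) or knockout B (0.254), with medians of 0.093 and 0.044. Oligodendrocyte lineage markers were called lower (12 of 17 lower, median -0.13, camera adjusted p = 0.00886, adjusted p = 0.226 with an estimated correlation), with -0.39 ± 0.12 for Opcml (paired adjusted p = 0.0238), -0.50 ± 0.18 for Gpr17, -0.27 ± 0.12 for Olig1 and -0.29 ± 0.14 for Pdgfra, and were lost without control C (0.0860). Their median was -0.050 without control C and -0.21 without control B.

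Microglial markers were called higher (18 of 21 higher, median 0.20, pair medians 0.58, 0.059 and 0.18, camera adjusted p = 0.00190, adjusted p = 0.226 with an estimated correlation). Their values were 0.52 ± 0.16 for the growth factor receptor Csf1r and 0.53 ± 0.19 and 0.55 ± 0.21 for the complement components C1qb and C1qc. Lpl, lipoprotein lipase, went the other way (-0.84 ± 0.20) and passed in the paired fit (adjusted p = 2.90e-07) and, unpaired, without knockout A (0.0118). Its control mean was 132 CPM, against 15.9 for Csf1r, 9.41 for C1qb and 11.7 for C1qc. Which cells of the tissue its reads came from was not resolved. The list was lost without control A (0.115) or knockout A (0.0873), and its median was 0.36 without control B and 0.31 without knockout B. Endothelial markers were called higher (15 of 20 higher, median 0.16, camera adjusted p = 0.0196, adjusted p = 0.226 with an estimated correlation), with 0.82 ± 0.34 for Tie1, 0.19 ± 0.11 for Slco1c1, 0.22 ± 0.13 for Flt1 and 0.40 ± 0.30 for Tek. They were lost without control A (0.243), knockout B (0.0710) or knockout C (0.154), with a median of 0.045 without control A and 0.27 without control B. Mural, meningeal and fibroblast markers did not pass unpaired (18 tested, median 0.34, camera adjusted p = 0.135) and passed paired (adjusted p = 4.82e-04, 0.409 with an estimated correlation), with 0.24 ± 0.11 for Rgs5, 0.48 ± 0.24 for Abcc9 and pair medians of 0.25, 0.0030 and 0.62. They passed unpaired without control B (0.00107) or knockout A (9.57e-04), with medians of 0.74 and 0.62, and had a median of -0.025 without control A. Their median was 0.20 without knockout B and 0.13 without knockout C. In the fatty acid synthesis, unfolded protein response, tricarboxylic acid, activity-regulated, channel, interneuron, radial glia, oligodendrocyte and endothelial lists, 0 members passed over all genes and 0 adjusted over the list alone. Of thyroid hormone-induced genes 1 passed over all genes, and 3 lower and 1 higher adjusted over the list alone, and of microglial genes 0 over all genes, and 1 lower and 1 higher adjusted over the list alone. In total 16 of 36 lists passed camera with its preset correlation, 6 higher and 10 lower, and without control C the balance turned (9 higher, 7 lower). None passed with an estimated correlation, where 7 had an unadjusted p under 0.05, and none passed fry's directional test, where 10 did. Camera with an estimated correlation also limits its degrees of freedom to those the few libraries leave. The interneuron list lost its call although its estimated correlation of 0.0026 was below the preset 0.01 (unadjusted camera p from 8.54e-07 to 0.00606). The lost calls therefore do not measure correlation between genes alone. With the letters paired, fry called 1 list, the upper-layer projection neurons (adjusted p = 0.0457), and paired camera with an estimated correlation called 0 (adjusted p = 0.396 for that list, 2 lists at an unadjusted p under 0.05).

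**Figure D2:**
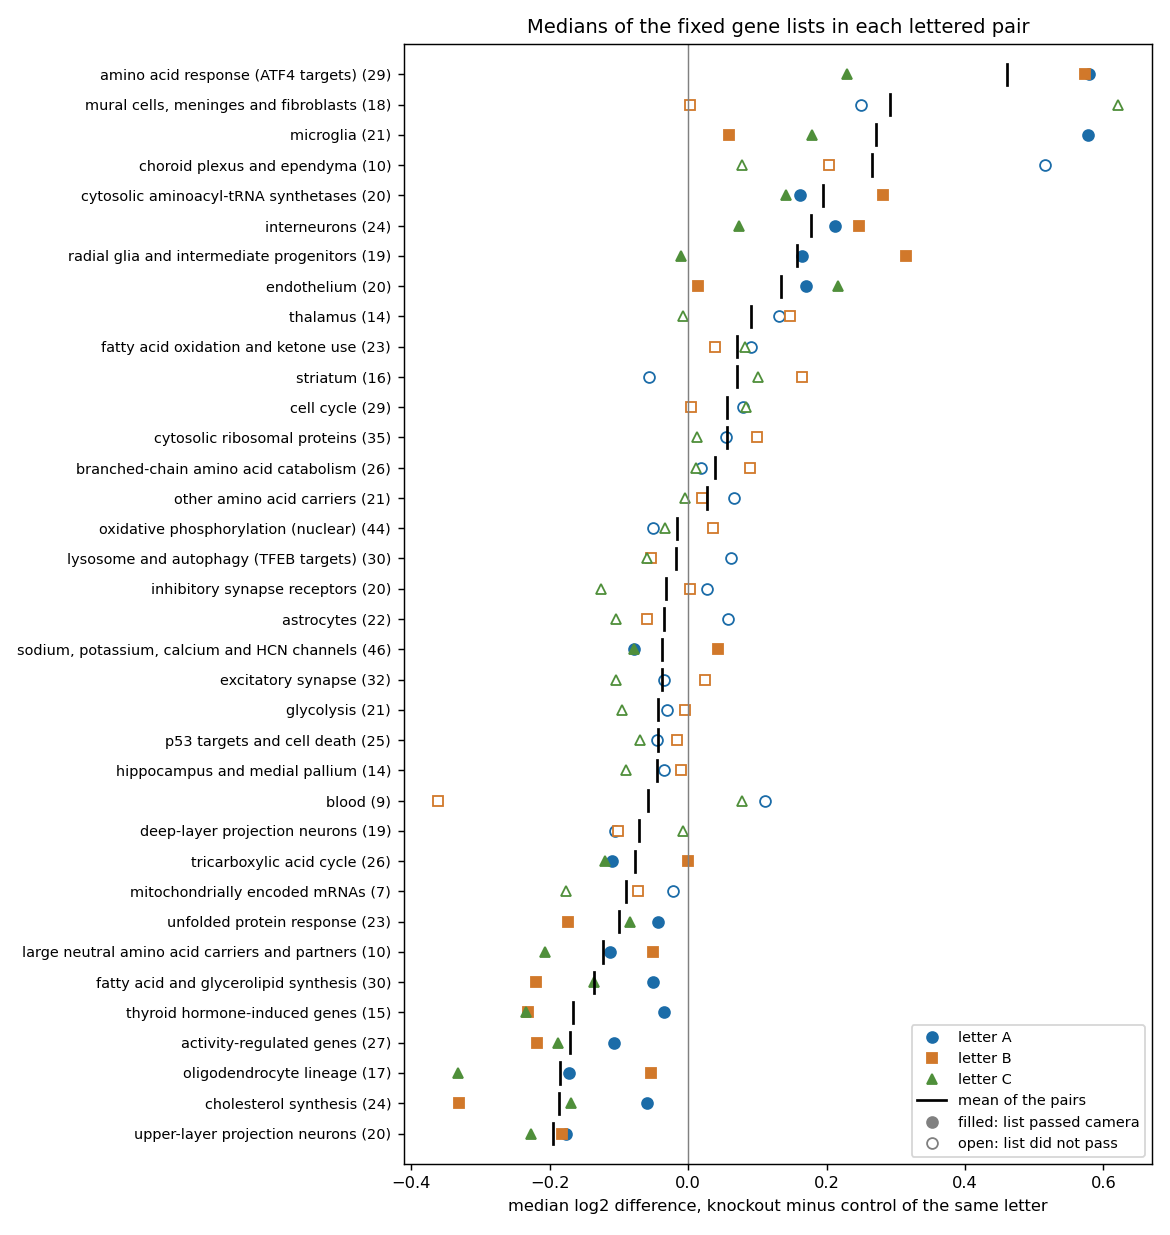
Median log2 difference of each of the 36 gene lists (x axis, knockout minus control of the same letter, number of tested members in brackets), with 1 symbol per letter and a black bar at the mean of the pairs. Filled symbols mark the 16 lists that passed camera with its preset correlation. By the mean of the pairs the amino acid response list lies farthest to the right, at 0.58, 0.57 and 0.23, and the upper-layer list farthest to the left, at -0.18, -0.18 and -0.23.

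The remaining pathway lists did not pass. Branched-chain amino acid catabolism (26 tested, median 0.019, camera adjusted p = 0.433) included Bcat1 (0.42 ± 0.11), which passed in the paired fit (adjusted p = 0.0319), and Acat1 (-0.24 ± 0.11). Fatty acid oxidation and ketone use (23 tested, 0.087, 0.249) had -0.31 ± 0.12 for Bdh1 and 0.38 ± 0.17 for Acadm. Its median was 0.045 without knockout C. Glycolysis (21 tested, -0.060, 0.249) had -0.29 ± 0.12 for Tpi1 and -0.25 ± 0.10 for Gpi1. It passed without control B (0.0388, median -0.11). Its median was -0.039, -0.030 and -0.034 without control A, control C and knockout B. Nuclear genes of oxidative phosphorylation (44 tested, -0.0060, 0.588) had -0.21 ± 0.11 for Atp5d and -0.19 ± 0.10 for Cox7a2. For lysosome and autophagy genes (30 tested, 0.021, 0.896), whose median was above 0 while camera's direction was down, Atp6v0d1 had -0.30 ± 0.12 and Rragd -0.24 ± 0.12. For p53 targets and cell death genes (25 tested, -0.029, 0.333), Hrk had 0.38 ± 0.11 and Plk2 -0.29 ± 0.10. The cell cycle list (29 tested, 0.063, 0.228) had 0.65 ± 0.30 for Hmmr and 0.63 ± 0.33 for Aurkb, and also passed without control B (0.0224), with medians from -0.0095 to 0.11 over all libraries left out in turn. The cytosolic ribosomal proteins (35 tested, 0.061, 0.216) had 0.32 ± 0.12 for Rpl23 and 0.30 ± 0.12 for Rpl5 (-0.038 with unstranded counts). Their median was 0.032 without control C and 0.011 without knockout A. The mitochondrially encoded mRNAs (7 tested, -0.031, 0.524) had -0.15 ± 0.093 for mt-Nd1 and -0.11 ± 0.10 for mt-Co1.

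Among the remaining cell type and region lists, astrocyte markers (22 tested, median -0.085, camera adjusted p = 0.228) had -0.86 ± 0.27 for Gpc5 and -0.27 ± 0.12 for Fgfr3, and passed as lower without control A (0.0212, median -0.18), while their median was 0.037 without control C and -0.051 without knockout A. Blood markers (9 tested, -0.074, 0.596) had a median below 0 and a mean of 0.18. Of them the neutrophil gene S100a8 (1.25 ± 0.35, 0.81 without knockout C) passed in the paired fit (adjusted p = 0.0336). Striatal markers (16 tested, 0.042, 0.596) had -0.35 ± 0.16 for Drd1 and 0.31 ± 0.22 for Six3. Hippocampal markers (14 tested, -0.043, 0.478) had -0.29 ± 0.11 for Spock1 and 0.29 ± 0.11 for Zbtb20. Their median was -0.11, -0.0036, -0.018 and -0.027 without control A, control B, knockout A and knockout C. Thalamic markers (14 tested, 0.095, 0.228) had 0.66 ± 0.41 for Gbx2 and 0.76 ± 0.45 for Zic1. They passed without control C (1.05e-08, median 0.14), as did Zic1 alone (3.69e-04, log2 change 1.33). Their median was 0.029 without control A and 0.025 without knockout C. Choroid plexus and ependymal markers (10 tested, 0.059, 0.228) had a median above 0, an upward direction in camera and a mean of -0.12, with 0.54 ± 0.27 for Otx2 and 0.42 ± 0.26 for Prlr. They passed without control B (0.0317) or control C (0.00265), with medians of 0.28 and 0.41, and had a median of -0.18 without control A. It was 0.12 without knockout A and 0.12 without knockout C. With 1 library left out the median also took the other sign in the blood, striatal, branched-chain catabolism, oxidative phosphorylation, lysosome, inhibitory synapse, p53 and mitochondrial lists, none of which passed in any of these fits. Leaving out 1 library also moved the values of other single genes that had not passed, among them Tek (0.012 without knockout A) and Six3 (0.080 without control B).

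Gm26812 (ENSMUSG00000097812, GRCm38 chromosome 8 from 121850194 to 121860621, plus strand), singled out after its values were seen, is annotated 20528 bp beyond the 3' end of Slc7a5 on the opposite strand. Control libraries held 1, 2 and 3 reads of it and knockouts 38, 40 and 14, a ratio of 14.2 with an exact conditional 95% interval of 6.26 to 39.6 that covers counting error only. It passed edgeR's test (adjusted p = 0.0196), but not without any 1 control, knockout A or knockout B (adjusted p from 0.0529 to 0.139), nor with limma-voom (0.0515). No reads lay on the strand opposite to it in any library. The tested neighbours Klhdc4 (-0.038 ± 0.11), Jph3 (-0.020 ± 0.11) and Banp (-0.093 ± 0.10) did not pass (adjusted p from 0.907 to 0.987).

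**Figure D3:**
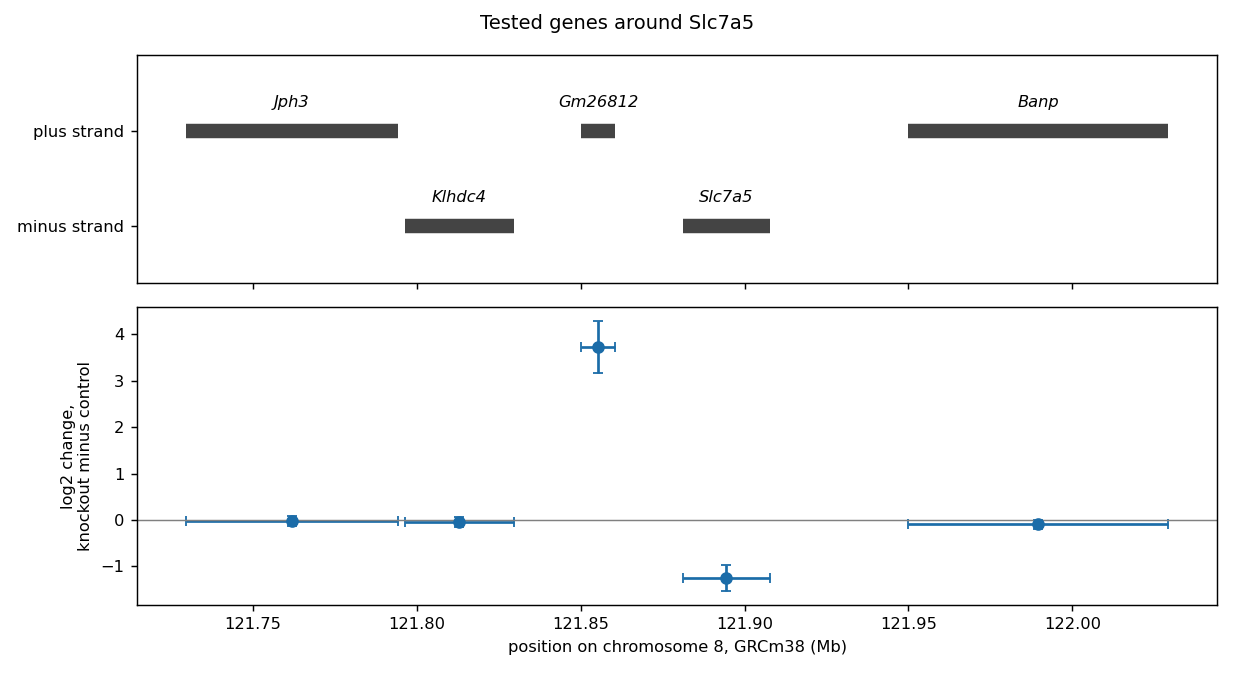
Tested genes around Slc7a5 on chromosome 8 of GRCm38 (x axis, Mb), by strand (top), with the fitted log2 change of knockout minus control and its SE (bottom; horizontal bars span the gene). Slc7a5 lies at -1.25 and Gm26812 at 3.74, a fitted value that rests on 6 control reads, while Jph3, Klhdc4 and Banp lie between -0.093 and -0.020.

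The libraries also differed in a measure outside the gene counts. The share of mapped reads outside annotated exons of the strand used, introns included, was 26.5%, 22.5% and 23.0% in controls A, B and C and 27.4%, 27.9% and 27.8% in knockouts A, B and C (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries allow). The 834 tested TEC loci moved with it, with median log2 differences of 0.061, 0.34 and 0.36 in pairs A, B and C. The share was higher in every knockout than in every control, so a fit that holds both can hardly separate them. With this share as a covariate, a fit chosen after the data were seen, no gene passed in edgeR (302 had an unadjusted p under 0.05) and 17 lists did, 12 higher and 5 lower, among them the amino acid response (median 0.48), the tRNA synthetases (0.14), the upper-layer list (-0.15) and the interneuron list (0.22). No list passed in it with an estimated correlation (lowest adjusted p = 0.194, for the amino acid response among others), and the microglial and endothelial medians were 0.65 and 0.46. The large neutral amino acid carriers, fatty acid synthesis, tricarboxylic acid cycle, unfolded protein response, activity-regulated and thyroid hormone-induced lists did not pass in it. It also called lists that had not passed before, among them the mural list (1.87), the choroid plexus list (1.13) and the astrocyte list (0.19) as higher and the striatal list (-0.22) as lower.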

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

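Both results here lie outside the gene counts used for the comparison, and the tests of the share of reads outside exons were chosen after that share was seen. No group has more than 3 libraries, so single libraries were not tested for standing apart.

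Reads on the strand opposite to Ankrd45 (ENSMUSG00000044835, GRCm38 chromosome 1 from 161142691 to 161170498, plus strand) were more numerous in the knockout. The opposite-strand counts, which the comparison does not use, held 5, 7 and 6 reads in controls A, B and C and 44, 62 and 40 in knockouts A, B and C, a log2 change of 2.82 ± 0.36 (SE, edgeR adjusted p = 6.81e-04, letters paired 5.73e-06). Among 2274 genes tested on that strand 1 passed, and 2 with the letters paired. The reads of Ankrd45 itself had a log2 change of -0.24 (edgeR adjusted p = 0.785). The annotation has Tex50 on the minus strand within this interval. No explanation was tested.

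The share of mapped reads outside annotated exons of the strand used, introns included, was 24.0% ± 2.17 in controls and 27.7% ± 0.272 in knockouts (SD, n = 3, exact permutation two-sided p = 0.1, the smallest possible). The pair differences were 0.921, 5.44 and 4.78 percentage points for A, B and C. TEC loci had a median log2 change of 0.26, and of -0.024 with the share in the fit. Control A lay closer to the knockouts than to the other controls, and the labels give no RNA quality values by which to compare libraries.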

How the results depend on the processing

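Chosen after seeing the data were the alternatives with protein-coding genes alone, with the share of reads outside exons in the fit, and those within the paired fit other than GC content and length offsets. The count of 5 genes became 126 with the letters as a block (49 higher, 77 lower), 131 with unstranded counts and the block, 111 with GC content and length offsets and the block, 9 with those offsets alone, 9 with upper-quartile scaling, 71 without the filter on low counts, 24 with DESeq2, 16 at an adjusted p under 0.1, and 0 with the share of reads outside exons in the edgeR fit (302 at an unadjusted p under 0.05). Leaving out 1 library gave 1 to 9. The split of 3 higher and 2 lower became 5 and 2 with RLE factors and 7 and 2 with upper-quartile scaling. The other settings gave 4 to 7 genes. The paired count of 126 became 30 with DESeq2 and 77 (46 higher, 31 lower, without pair C) to 228 without 1 lettered pair, and 96 to 131 in the other paired fits. Slc7a5 kept its direction in 14 of 14 alternatives and passed in 2, without the filter (log2 change -1.25) and with DESeq2 (-1.26), with adjusted p from 5.02e-11 to 0.679 over all of them. Without 1 library its log2 change was -1.47 to -0.93. The count of 16 lists became 0 with an estimated correlation (7 at an unadjusted p under 0.05) and 0 with fry (10), and 11 to 21 without 1 library. The block added the excitatory synapse and mural lists, 17 named genes and no other call among those results. Unpaired, Sesn2 and Chac1 also passed with unstranded counts, RLE factors, upper-quartile scaling, either other filter and DESeq2. Dok4, Grm2, Rorb, Cars and Lpl passed without the filter and with DESeq2, and Kcnn1, Gad2 and S100a8 without the filter. Of the lists that had not passed, the oxidative phosphorylation, excitatory synapse, inhibitory synapse, p53 and mitochondrial medians took the other sign with upper-quartile scaling, the p53 and hippocampal medians without the filter, and the other carrier, excitatory synapse and deep-layer medians without the genes in more than 1 list. Of the called lists, 2 had medians of the other sign where they were no longer called, the thyroid hormone-induced list at 0.027 with the share of reads outside exons in the fit and the channel list at 0.0072 without control A. Fewer libraries leave less information to the fits that omit some, and the cause of the other changes was not tested. At this depth and n, 1.5-fold changes of single genes were mostly missed by the unpaired fit in simulated data (18.4% found).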

Other observations

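Emx1, whose promoter drives the recombinase, had a log2 change of -1.05 ± 0.22 (SE, edgeR adjusted p = 0.179, 1.75e-04 with the letters paired), with 18.7 ± 6.05 CPM in controls and 8.99 ± 1.61 CPM in knockouts (SD, n = 3). BC048644, a noncoding RNA that starts beside the promoter of Slc7a5, was too low to be tested and had 4, 7 and 9 reads in controls A, B and C and 1 read in each knockout. Both were singled out after their values were seen.

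Of the tests that follow, those on all splits for lists and for paired genes, on the share of reads outside exons, on the unfolded protein response and on the share of projection neurons were chosen after the results were seen.

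The unpaired fit called 5 genes, and 2 of the 10 splits of the 6 libraries into 3 and 3 gave as many, the real one included. The highest other split called 96. It set control A, knockout A and knockout C against the rest. So many calls point to a structure of the samples other than genotype, whose nature was not tested. Another split with pairs A and B on opposite sides, control A, control C and knockout A against the rest, called 2. With the letters paired, 1 of the 4 splits that part every pair gave as many as the real 126, and the highest other gave 1. For lists 1 of 10 splits gave 16, and the highest other gave 9. These splits are too few for a share under 0.05.

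The tables argue against unequal sexes as the cause of these gene calls, since Xist was above 10 CPM in 1 knockout and 1 control library. With offsets for GC content and length 9 genes were called, against 5 without, so the number of calls did not fall. Whether the 5 were among the 9 was not compared, so the count cannot decide about GC content or gene length for single calls. Called genes within 10 Mb of Emx1, Emx1 itself left out, where variants of the strain in which the Cre allele was made could travel with it, had a Fisher odds ratio of 1.53 with the letters paired (95% interval 0.182 to 5.76, 2 of 157 tested genes). Such variants cannot be told apart from an effect of the knockout for those genes, because the calls there are too few.

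The rise of the amino acid response list was weighed against 2 explanations. With the share of reads outside exons in the fit its median log2 change was 0.48 against 0.52 without. That fit can hardly separate share and genotype (correlation 0.827), so it cannot decide whether the share accounts for the rise. In pairs A, B and C the list medians were 0.58, 0.57 and 0.23. The share differences were 0.921, 5.44 and 4.78 percentage points, so the rise did not grow with the share difference. Endoplasmic reticulum stress, another trigger of ATF4, would raise the unfolded protein response list, whose pair medians averaged -0.10 ± 0.067 (SD, 3 pairs), which runs against that trigger. A shortage of amino acids inside cells that lost the carrier is a candidate explanation and was not tested.

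The fall of upper-layer markers and the rise of interneuron markers were weighed likewise. The upper-layer median was -0.15 with the share of reads outside exons in the fit, against -0.20 without, and that fit cannot decide here either. A lower share of projection neurons alone would raise the markers of other cell types alike. The interneuron median exceeded that of the oligodendrocyte lineage by 0.363 ± 0.0556 (SD, 3 pairs). Emx1-driven Cre partly reaches that lineage, so the gap cannot decide whether projection neurons were fewer. The microglial and endothelial medians were 0.20 and 0.16, and that of blood markers -0.074. A lower share of projection neurons, fewer oligodendrocyte lineage cells, a change in the interneurons themselves or lower expression within upper-layer neurons stay open.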
